A study of Mus musculus with 18 samples.

How the data were processed

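Total RNA of primary hepatocytes (MPH), biliary epithelial cells (BECs) and Kupffer-like cells from the livers of sham-operated (Sham) and bile duct ligated (BDL) mice was extracted with TRIzol, and polyadenylated RNA libraries were made with the VAHTS Universal V6 kit, per the labels. Per the labels, the authors called bases with CASAVA 1.8, trimmed reads with fastp, aligned them to GRCm38 (mm10) with HISAT2 2.0.5, counted them per gene with featureCounts 1.5.0-p3 and used DESeq2 1.20.0. The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to library size) for 54532 genes in 18 columns, 1 per library, which the authors computed from those counts. The version of fastp, the annotation release, the strandedness and the time after ligation are not given in the sources used here. Groups were taken from the cell type and treatment labels, 6 groups of 3 libraries. Hepatic stellate cells were not analysed here.

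The library size behind each column was recovered from the deposited FPKM values and the exon-union lengths of GENCODE M21, as the size at which FPKM times length gives whole reads. Of 53710 genes with a unique symbol and a length, 52730 (98.2%) had whole reads in all libraries within a tolerance of 0.02. Of the single values below 200 reads, 97.4% to 98.4% were whole, depending on the library. Recovered reads in genes ran from 15455411 to 20583319 per library and implied library sizes from 8640613 to 22122621. The implied sizes had a correlation of 0.999 with median ratio factors over 14032 genes and 0.108 with the read totals. The ratio of implied size to read total was 0.516 to 0.741 in MPH and 0.934 to 1.22 in the other cell types, so the deposited values were taken as scaled by a median ratio method and not per total. Replicate libraries differed by more than read sampling, with a chi-square per degree of freedom of 18.1 to 239 over genes. Among the symbols, 105 repeated an earlier one and 27 looked like dates. These were kept as separate genes.

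Values were analysed as log2(FPKM + 1). In each comparison, genes with FPKM of at least 1 in at least 3 of its libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust, 2-sided), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. BDL was compared with Sham in the 6 libraries of each cell type. Differences of the response were tested as an interaction over the 12 libraries of 2 cell types, and cell type identity over the 9 Sham libraries, where a gene counted when it was higher than in both other cell types. Common genes were counted against the number expected for independent lists. Of 41 gene lists, 40 were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, in each cell type with at least 5 tested members. This made 113 tests, adjusted together. The list of sex-linked genes was not tested, and the sex of each library was read from the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Members were also counted after adjustment over the list alone.

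The gene lists, the comparisons, the other settings to be tried and the rule for named genes were chosen before the data were examined. The rule took the 5 largest rises and 5 largest falls among called genes with a mean FPKM of at least 5 in the higher group, groups that do not overlap and no predicted-gene name. It added 7 genes of known function per cell type whatever their result, up to 4 called members per list (or the 2 with the smallest p), 3 genes per direction of each difference, and 5 common genes per direction. The results of 3 genes that this rule takes are not reported here. The other settings were pseudocounts of 0.1 and 0.01, no filter on level, FPKM of at least 5, scaling to a common sum, median ratio scaling, quantile normalization, eBayes without trend and robust and a fold threshold. Others were limma voom, all 18 libraries in 1 model, marker covariates (hepatocyte markers, Kupffer cell markers), the number in the titles as a block through duplicateCorrelation (statmod 1.5.0), and leaving out each library. Chosen after the data were examined were scaling to recovered reads, sex as a covariate, endothelial markers and B and plasma cell markers as covariates, and leaving out libraries in the correlations. Voom was planned for lengths given in the table, which has none, and was run with annotation lengths instead. DESeq2 and edgeR were not used here, since no count table was used.

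The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 37% and 91% of them in MPH, 85% and 92% in BECs and 92% and 95% in Kupffer-like cells, with 19, 19 and 18 false calls. For differences of the response it recovered 16.2% and 84.7% (MPH and BECs), 20.4% and 87% (MPH and Kupffer-like cells) and 65% and 91.9% (BECs and Kupffer-like cells), with 14, 13 and 11 false calls. The simulated reads had 1 dispersion per cell type, taken from its Sham libraries (0.0564 in MPH, 0.0267 in BECs and 0.0130 in Kupffer-like cells). Kupffer BDL libraries differed more from each other (chi-square per degree of freedom of 109 to 237) than Kupffer Sham libraries (18.1 to 67.1). Recovery in the real data can therefore be lower than in the simulation. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.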

Results

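Polyadenylated RNA was sequenced from 3 kinds of cells isolated from mouse liver, after ligation of the bile duct (BDL), a surgical model of blocked bile flow, or after a sham operation (Sham). The cells were primary hepatocytes (MPH), biliary epithelial cells (BECs), which line the bile ducts, and Kupffer-like cells, named for the resident macrophages of the liver. Each of the 6 groups held 3 libraries, 18 in all. Hepatic stellate cells, which the study design also names, were not analysed here. Between 15455411 and 20583319 reads in genes were recovered per library from the deposited FPKM values. The labels give neither the time after ligation nor whether each library came from a separate mouse, so p-values measure the spread between these libraries only.

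The Sham libraries were compared first, to ask whether each preparation carried the transcripts of its named cell type. Alb, the gene of serum albumin, stood at 49899 ± 28263 FPKM in MPH, 1811 ± 900.2 in BECs and 469.9 ± 147 in Kupffer-like cells (mean ± SD, n = 3 per group, as throughout). Krt19, a keratin of bile duct cells, stood at 478 ± 102 FPKM in BECs against 3.05 ± 0.376 in MPH and 3.26 ± 1.83 in Kupffer-like cells. Clec4f, a lectin of Kupffer cells, stood at 1626 ± 164 FPKM in Kupffer-like cells, 733 ± 351 in MPH and 11.2 ± 6.17 in BECs. With limma, 16 of 16 hepatocyte markers were higher in MPH than in both other cell types, and 15 of 15 biliary markers were higher in BECs. Only 3 of 12 Kupffer cell markers were higher in Kupffer-like cells than in both others, namely Clec4f and the scavenger and complement receptors Vsig4 and Cd163. The median Kupffer marker in MPH reached 62.1% of its level in Kupffer-like cells, with a range over markers of 45.1% to 153%. Without MPH Sham 1 the median was 39.8% (33.9% to 44.7%).

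Over all 14466 genes tested in the Sham libraries, 3102 were higher in MPH, 2318 in BECs and 1898 in Kupffer-like cells than in both other cell types. Those counts moved to 1559, 2567 and 2916 when each library was scaled to its recovered reads, and 11 of 12 Kupffer markers then passed. Without BECs Sham 1, 2 or 3 the BECs count was 1276, 1203 or 1527, and the Kupffer count was 1211 without Kupffer Sham 2 and 1104 without Kupffer Sham 3. The marker count of 3 became 12 without MPH Sham 1, 1 without BECs Sham 1, BECs Sham 2 or Kupffer Sham 2, and 0 by limma without MPH Sham 2, MPH Sham 3, Kupffer Sham 1 or Kupffer Sham 3, where 1, 1, 3 and 1 markers had an unadjusted p under 0.05.

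**Figure D1:**
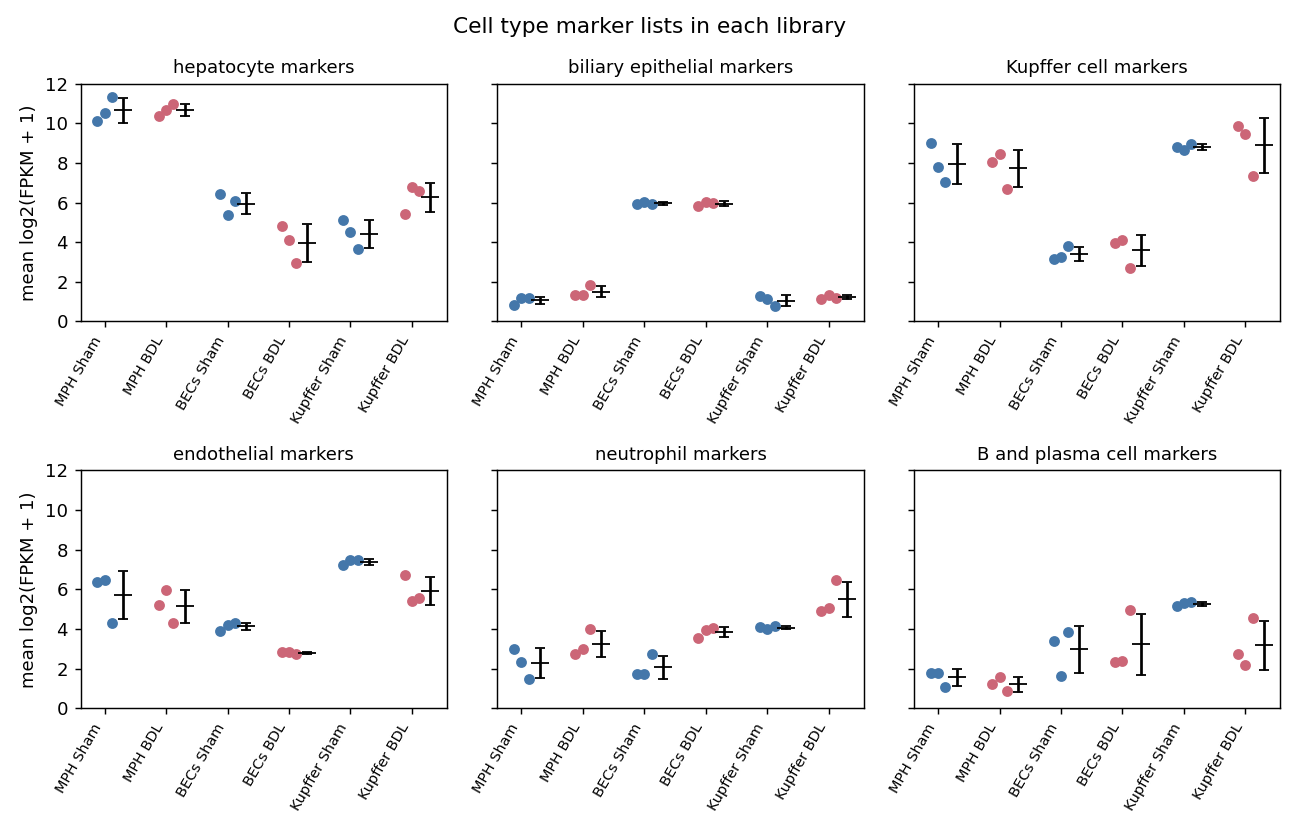
Mean log2(FPKM + 1) over the members of 6 marker lists, 1 dot per library, blue for Sham and red for BDL, with the mean ± SD of the 3 libraries beside each group in black. Hepatocyte markers stood near 10.7 in both MPH groups, moved from 5.95 to 3.96 in BECs and from 4.41 to 6.28 in Kupffer-like cells, and Kupffer cell markers stood at 7.94 in MPH Sham against 8.80 in Kupffer Sham.

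In hepatocytes, the largest rises after ligation were those of Lcn2 and Sult1e1, and the largest falls those of Car3, Mup3 and Sult2a8. Here and below changes are ranked as log2(FPKM + 1), so the order depends on the offset of 1 FPKM where a group is near 0. Lcn2, whose product lipocalin 2 binds bacterial siderophores, rose from 40.1 ± 48.4 to 1101 ± 319 FPKM (log2 fold change 5.40, standard error 0.79, adjusted p = 0.0358 with limma). Sult1e1, the estrogen sulfotransferase, rose from 0.0425 ± 0.0736 to 43.0 ± 20.9 FPKM (log2 fold change 5.30, standard error 0.32, limma adjusted p = 0.00155). The other large rises were Ms4a4a, a membrane protein of macrophages (4.07), Serpina7, the thyroxine-binding globulin (3.88), and Timp1, an inhibitor of matrix metalloproteinases (3.77, from 1.24 ± 0.476 to 29.2 ± 1.17 FPKM). Car3, a carbonic anhydrase, fell from 739 ± 583 to 3.17 ± 3.62 FPKM (log2 fold change -7.64, standard error 0.82). Falls were also seen for Sult2a8, a liver sulfotransferase, from 179 ± 104 to 0.237 ± 0.135 FPKM (-7.04), and Fabp1, the liver fatty acid binding protein, from 4662 ± 1690 to 173 ± 227 FPKM (-5.58). The major urinary protein genes Mup3 and Mup11, members of a family of near-identical copies whose reads are hard to assign, had log2 fold changes of -7.09 and -5.72. In the GRCm38 annotation Lcn2 spans chromosome 2, 32384633 to 32388252, Sult1e1 chromosome 5, 87575969 to 87591594, and Car3 chromosome 3, 14863512 to 14872523, all protein-coding.

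Genes of bile acid handling were followed whatever their result. Cyp8b1, the enzyme that directs bile acid synthesis toward cholic acid, fell from 141 ± 113 to 3.84 ± 3.64 FPKM (log2 fold change -4.93, standard error 0.86, limma adjusted p = 0.0494). Cyp7a1, the rate-limiting enzyme of the classical pathway, was at 20.5 ± 16.0 FPKM in Sham and 23.7 ± 34.9 in BDL and did not pass (limma adjusted p = 0.738). The uptake carrier Slc10a1, the canalicular pump Abcb11, the basolateral exporters Abcc4 and Slc51b and the nuclear receptor Nr0b2 had log2 fold changes of -0.50, -1.08, 0.44, 0.68 and -2.83, none past the threshold. Of the 15 tested genes of bile acid synthesis 1 fell, Cyp8b1, and 4 passed when adjusted over the list alone (camera adjusted p = 0.0627 for the list, adjusted p = 0.646 with an estimated correlation). Of 8 carriers of bile acid and organic anion uptake, Slc22a7 was among those that fell (-3.64), and 3 passed adjusted over the list alone (camera adjusted p = 0.0703, adjusted p = 0.593 with an estimated correlation). Among 12 bile acid and lipid exporters the sterol transporter Abcg8 fell (-1.40) and 1 passed adjusted over the list alone (camera adjusted p = 0.730, adjusted p = 0.925 with an estimated correlation).

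Lists of inflammatory and matrix genes stood higher as groups in MPH after ligation. The 21 acute phase genes all had positive changes, with a mean of 2.09. Steap4, a metalloreductase, (2.78), Lcn2 and Cp, the ferroxidase ceruloplasmin, (2.60) rose. When adjusted over the list alone 18 passed (camera adjusted p = 1.63e-12, adjusted p = 0.369 with an estimated correlation). Of 28 extracellular matrix and fibrosis genes 5 rose: Timp1, Lox, which crosslinks collagen (2.95), Mmp2 (2.35), Thbs1 (3.76) and, named after its value was seen, Tnc (1.22). In this list 10 passed adjusted over the list alone (camera adjusted p = 6.61e-11, adjusted p = 0.434 with an estimated correlation). Of 22 cytokine and chemokine genes Cxcl2 (2.95), Osm (1.54), Ptgs2 (2.39) and Il6 (2.87) rose. In all 8 passed adjusted over the list alone, 6 of them higher and 2 lower (camera adjusted p = 0.000466, adjusted p = 0.593 with an estimated correlation). Markers of other cells moved in the same libraries. F13a1 (1.96) and Chil3 (3.01) rose among 6 monocyte markers, 4 of which passed adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.434 with an estimated correlation). None of 9 neutrophil markers or 13 stellate and fibroblast markers passed by limma, with means of 1.06 and 1.18, and 0 and 4 passed adjusted over the list alone (camera adjusted p = 0.00400 and 5.72e-05, adjusted p = 0.593 and 0.545 with an estimated correlation). The 12 Kupffer cell markers had a mean change of -0.22 with none passing, over all genes or adjusted over the list alone (camera adjusted p = 0.933, adjusted p = 0.986 with an estimated correlation), and the 16 hepatocyte markers one of 0.02, with 0 passing over all genes and 2 adjusted over the list alone (camera adjusted p = 0.888, adjusted p = 0.980 with an estimated correlation).

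Lipid and interferon genes stood lower as groups in MPH. All 23 genes of cholesterol synthesis and uptake had negative changes, with a mean of -1.01. The pathway enzymes Tm7sf2 (-2.27) and Pmvk (-1.88) fell, and 12 passed adjusted over the list alone (camera adjusted p = 2.34e-06, adjusted p = 0.545 with an estimated correlation). Of 16 fatty acid oxidation genes the peroxisomal thiolase Acaa1b fell (-3.55, from 709 ± 96.9 to 62.0 ± 23.6 FPKM), and of 15 lipogenesis genes Thrsp (-3.18), with 5 of each list passing adjusted over the list alone (camera adjusted p = 0.00400 for each, adjusted p = 0.632 and 0.593 with an estimated correlation). All 20 interferon response genes had negative changes, with a mean of -1.28, and Stat2, a signal transducer of type I interferon, fell (-1.13). Adjusted over the list alone 11 passed (camera adjusted p = 2.01e-06, adjusted p = 0.582 with an estimated correlation). The 16 tested cell cycle genes had a mean change of -0.78, from a low level (mean log2(FPKM + 1) of the whole list 1.93 in Sham and 1.21 in BDL), with 0 passing by limma and 1 adjusted over the list alone (camera adjusted p = 8.50e-05, adjusted p = 0.545 with an estimated correlation). Beside these lists, the 11 endothelial markers had a mean change of -0.57, with none passing, over all genes or adjusted over the list alone (camera adjusted p = 0.376, adjusted p = 0.885 with an estimated correlation).

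Over all 12323 genes tested in MPH, limma called 194, of which 88 rose and 106 fell, and 2791 had an unadjusted p under 0.05. The groups did not overlap for 3722 genes (30.2%), where chance gives 10%. The split between rises and falls depended on the scaling, with 73 and 42 after scaling to a common sum, which moved the median of all genes by 0.17 log2 units, and 50 and 46 after scaling to recovered reads. Leaving out MPH Sham 1, 2 or 3 gave 20, 22 or 25 called genes, and leaving out MPH BDL 1, 2 or 3 gave 77, 8 or 34. With all genes above 0 tested 18 were called, with a pseudocount of 0.01 there were 59, and with all 18 libraries in 1 model about 2.2e+03.

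In biliary epithelial cells, Reg3b and Clec4e were among the 5 largest rises after ligation, and Fabp1, Mup3 and Spink4 had the largest falls. Reg3b, an antibacterial lectin, rose from 1.06 ± 0.805 to 47.2 ± 47.0 FPKM (log2 fold change 4.09, standard error 0.77, limma adjusted p = 0.0333). Clec4e, the pattern recognition receptor Mincle, rose from 2.82 ± 0.698 to 48.5 ± 10.1 FPKM (log2 fold change 3.69, standard error 0.20, limma adjusted p = 0.00177). The protease gene Asprv1 (3.27) and the acute phase serpin Serpina3n (3.24, from 28.8 ± 3.92 to 360 ± 255 FPKM) also rose, as did Mir7678 (4.04), a microRNA gene on the same strand as the overlapping gene Slpi, whose reads cannot be told from its own here. Fabp1 fell from 105 ± 50.5 to 0.956 ± 0.840 FPKM (log2 fold change -5.76, standard error 0.49), Spink4, a protease inhibitor, from 104 ± 74.8 to 3.43 ± 2.11 FPKM (-4.44), and S100g, a calcium-binding protein, from 66.7 ± 29.5 to 2.67 ± 1.94 FPKM (-4.22). Mup3 (-5.65) and Serpina1e (-4.29) belong to families of near-identical copies. Reg3b lies on chromosome 6, 78370657 to 78373466, Clec4e on chromosome 6, 123281789 to 123289870, and Spink4 on chromosome 4, 40920052 to 40931395.

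Of the biliary genes followed whatever their result, Cftr, the chloride channel of bile duct cells, rose from 4.26 ± 0.735 to 10.9 ± 3.69 FPKM (log2 fold change 1.14, standard error 0.24, limma adjusted p = 0.0398). The keratins Krt7 and Krt19, the transcription factor Sox9, the adhesion molecule Epcam, the matrix protein Spp1 and the proliferation marker Mki67 had log2 fold changes of 0.50, -0.34, -0.35, 0.02, -0.41 and 1.22, none past the threshold. Of 15 biliary markers Cftr rose, and 7 passed adjusted over the list alone, 3 higher and 4 lower (camera adjusted p = 0.541, adjusted p = 0.754 with an estimated correlation). Of 12 genes of biliary bicarbonate and bile acid transport, Cftr rose and the water channel Aqp1 (-1.13) and Adcy6 (-0.64) fell, with 4 passing adjusted over the list alone (camera adjusted p = 0.150, adjusted p = 0.624 with an estimated correlation).

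Genes of myeloid cells and cytokines stood higher as groups in BECs. Of 25 cytokine and chemokine genes 7 rose and 1 fell, and 12 passed adjusted over the list alone. The neutrophil chemokine Cxcl2 (2.68, from 71.8 ± 13.3 to 469 ± 108 FPKM), Osm (2.46), Il1a (2.34) and Il1b (2.00) had the smallest p (camera adjusted p = 2.21e-07, adjusted p = 0.545 with an estimated correlation). Of 9 neutrophil markers 5 rose: Csf3r (2.19), Mmp9 (1.99), S100a9 (2.82), S100a8 (3.13) and, named after its value was seen, Cxcr2 (1.30). Of the 9, 7 passed adjusted over the list alone (camera adjusted p = 1.02e-06, adjusted p = 0.434 with an estimated correlation). Itgam (1.82) and F13a1 (2.20) rose among 8 monocyte markers, 6 of which passed adjusted over the list alone (camera adjusted p = 6.22e-05, adjusted p = 0.369 with an estimated correlation). Of 30 extracellular matrix and fibrosis genes Timp1 (2.97), the growth factor Pdgfb (1.44) and the collagen Col5a2 (1.24) rose, and 12 passed adjusted over the list alone (camera adjusted p = 2.06e-05, adjusted p = 0.593 with an estimated correlation). Of 22 cell cycle genes 21 had positive changes, with a mean of 0.69. Ccnb1, a mitotic cyclin, rose (1.204), and 1 passed adjusted over the list alone (camera adjusted p = 2.01e-06, adjusted p = 0.593 with an estimated correlation). All 10 markers of lipid- and scar-associated macrophages had positive changes, with a mean of 0.95, and 7 passed adjusted over the list alone (camera adjusted p = 0.000265, adjusted p = 0.434 with an estimated correlation). Of 9 T and NK cell markers 7 had positive changes, with a mean of 0.47, and 4 passed adjusted over the list alone (camera adjusted p = 0.0311, adjusted p = 0.593 with an estimated correlation). Kupffer cell markers, 10 tested, had a mean change of 0.22 and none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.214, adjusted p = 0.770 with an estimated correlation).

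Hepatocyte, endothelial and immediate early genes stood lower as groups in BECs. All 16 hepatocyte markers had negative changes, with a mean of -1.99. Ttr, the thyroid hormone carrier transthyretin, fell (-2.18, from 278 ± 69.3 to 61.0 ± 18.0 FPKM), and 13 passed adjusted over the list alone (camera adjusted p = 2.34e-06, adjusted p = 0.545 with an estimated correlation). Beside them, 4 of 15 genes of cytochrome P450 drug metabolism fell, Cyp1a2 (-3.82), Cyp2d10 (-2.70), Cyp3a13 (-1.68) and Cyp2c37 (-2.99). Of the 15, 12 passed adjusted over the list alone (camera adjusted p = 8.85e-06, adjusted p = 0.469 with an estimated correlation). Of 14 bile acid synthesis genes Akr1c6 (-3.50), Cyp8b1 (-2.28), Amacr (-0.97) and Cyp39a1 (-0.64) fell, with 10 passing adjusted over the list alone (camera adjusted p = 5.58e-05, adjusted p = 0.545 with an estimated correlation). Of 11 endothelial markers 8 fell, among them Oit3 (-2.32), Dnase1l3 (-2.23), Gpr182 (-1.65) and Clec4g (-2.29). Of the 11, 10 passed adjusted over the list alone (camera adjusted p = 4.39e-06, adjusted p = 0.369 with an estimated correlation). The immediate early transcription factors Atf3 (-1.10), Jun (-1.03), Fos (-0.86) and Egr1 (-0.84), which also respond to tissue dissociation, fell among 14 such genes, with 7 passing adjusted over the list alone (camera adjusted p = 7.57e-05, adjusted p = 0.469 with an estimated correlation). Ifi44 was among those that fell (-1.13) of 20 interferon response genes, with 4 passing adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.624 with an estimated correlation).

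Over all 13573 genes tested in BECs, limma called 1040, of which 402 rose and 638 fell, and 3526 had an unadjusted p under 0.05. The groups did not overlap for 4323 genes (31.9%), against 10% by chance. After scaling to a common sum 449 rose and 388 fell, and after scaling to recovered reads 521 rose and 463 fell. Without BECs Sham 1, 2 or 3 the count was 86, 357 or 636, without BECs BDL 1 or 2 it was 255 or 407, and with all genes above 0 tested it was 81. With the mean of the hepatocyte markers as a covariate 8 genes were called, with sex as a covariate 576, and 576 of the 1040 changed at least 2-fold. The hepatocyte covariate did not overlap between Sham (5.37 to 6.41) and BDL (2.94 to 4.83), so it also takes up the treatment contrast.

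In Kupffer-like cells, the acute phase genes Saa2 and Saa1 had the largest rises after ligation, and Ltbp4 and Ehd3 the largest falls. Saa2, a serum amyloid gene, rose from 0.450 ± 0.461 to 139 ± 153 FPKM (log2 fold change 6.07, standard error 0.74, limma adjusted p = 0.0250), and Saa1, a close copy whose reads are hard to tell from its own, by 5.40. Hamp, the iron hormone hepcidin, rose from 11.3 ± 8.91 to 252 ± 123 FPKM (log2 fold change 4.72, standard error 0.86, limma adjusted p = 0.0445). Orm1, an acute phase glycoprotein, (4.03) and Ms4a4a (3.98, from 4.57 ± 1.71 to 96.4 ± 60.1 FPKM) also rose. Ltbp4, which binds latent TGF-beta, fell from 162 ± 47.9 to 19.1 ± 14.8 FPKM (log2 fold change -3.22, standard error 0.54, limma adjusted p = 0.0412). Ehd3, an endocytic protein, fell from 208 ± 20.7 to 28.1 ± 7.05 FPKM (-2.86). Further falls were those of Cxcl9, a chemokine induced by interferon gamma, from 31.0 ± 6.69 to 3.68 ± 1.41 FPKM (-2.80), the protocadherin Pcdh12 by a change of -2.62 and the nuclease Dnase1l3 by one of -2.56. Dnase1l3 is one of the endothelial markers, whose mean log2(FPKM + 1) was 7.39 in Kupffer Sham, 5.71 in MPH Sham and 4.13 in BECs Sham. In Kupffer BDL this mean was 5.91. Whether RNA of endothelial cells made up part of the falls was not tested. Saa2 lies on chromosome 7, 46751790 to 46754313, Hamp on chromosome 7, 30942368 to 30944032, and Ehd3 on chromosome 17, 73804134 to 73832094.

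Genes that mark resident and recruited macrophages were followed whatever their result. Ccr2, the chemokine receptor of inflammatory monocytes, rose from 8.48 ± 1.195 to 21.1 ± 5.99 FPKM (log2 fold change 1.195, standard error 0.23, limma adjusted p = 0.0469). The resident markers Clec4f, Vsig4 and Timd4 had log2 fold changes of -0.93, 0.05 and -0.04, the lipid receptor Trem2 1.39, the cytokine Il1b 1.22 and Spp1 0.23, none past the threshold. The 12 Kupffer cell markers had a mean change of 0.09 and a median of -0.01, with none passing over all genes or adjusted over the list alone (camera adjusted p = 0.888, adjusted p = 0.980 with an estimated correlation). The BDL libraries stood apart from each other, with a mean log2(FPKM + 1) over these markers of 9.89 and 9.45 in Kupffer BDL 1 and 2, above the 8.65 to 8.97 of Sham, and 7.32 in Kupffer BDL 3. Vsig4 stood at 1380, 1096 and 167 FPKM in them. F13a1 (2.11) and Ccr2 rose among 8 monocyte markers, 4 of which passed adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.434 with an estimated correlation). Mmp8 (2.60), Retnlg (2.55), S100a8 (2.04) and Cxcr2 (2.05) rose among 9 neutrophil markers, 5 of which passed adjusted over the list alone (camera adjusted p = 7.93e-05, adjusted p = 0.545 with an estimated correlation). Gpnmb (2.45) and Lgals3 (1.58) rose among 10 markers of lipid- and scar-associated macrophages, 5 of which passed adjusted over the list alone (camera adjusted p = 0.00650, adjusted p = 0.469 with an estimated correlation).

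All 21 acute phase genes had positive changes in Kupffer-like cells, with a mean of 3.05, and 8 rose, among them Orm2 (3.32), Saa2, Lcn2 (3.49) and Saa1. Adjusted over the list alone 18 passed (camera adjusted p = 4.31e-11, adjusted p = 0.521 with an estimated correlation). In the same libraries all 16 hepatocyte markers had positive changes, with a mean of 1.86, among them Alb, at 469.9 ± 147 FPKM in Sham and 1449 ± 764 in BDL. Of these 0 passed by limma and 6 adjusted over the list alone (camera adjusted p = 8.85e-06, adjusted p = 0.545 with an estimated correlation). All 14 NRF2 and glutathione genes had positive changes, with a mean of 1.33. The reductases Gsr (2.04, from 40.3 ± 2.55 to 172 ± 38.8 FPKM) and Txnrd1 (1.25) rose, and 9 passed adjusted over the list alone (camera adjusted p = 3.81e-06, adjusted p = 0.369 with an estimated correlation). Of 27 extracellular matrix and fibrosis genes 6 rose, among them Acta2 (1.797), Thbs1 (2.68), Col6a1 (2.16) and Lox (2.86). Of the 27, 14 passed adjusted over the list alone, 13 higher and 1 lower (camera adjusted p = 0.00250, adjusted p = 0.409 with an estimated correlation). The mesothelial markers Upk1b (2.74), Upk3b (1.38) and Wt1 (1.08) rose, and all 5 tested passed adjusted over the list alone (camera adjusted p = 0.000214, adjusted p = 0.434 with an estimated correlation).

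Interferon, endothelial and lymphocyte genes stood lower as groups in Kupffer-like cells. All 20 interferon response genes had negative changes, with a mean of -1.07, and 10 fell, among them the antiviral genes Ifit2 (-1.57, from 29.4 ± 2.91 to 9.25 ± 0.999 FPKM), Xaf1 (-1.16), Ifit1 (-1.62) and Gbp3 (-0.87). Adjusted over the list alone 16 passed (camera adjusted p = 1.63e-12, adjusted p = 0.409 with an estimated correlation). Of 22 cytokine and chemokine genes the interferon-induced Cxcl9 and Cxcl10 (-1.69) fell and Cxcl2 rose (1.93), with 4 passing adjusted over the list alone (camera adjusted p = 0.137, adjusted p = 0.612 with an estimated correlation). Of 11 endothelial markers the VEGF receptor Kdr (-2.11), Dnase1l3, Gpr182 (-2.02) and the scavenger receptor Stab2 (-1.28) fell. Of the 11, 7 passed adjusted over the list alone (camera adjusted p = 2.34e-06, adjusted p = 0.545 with an estimated correlation). All 7 B and plasma cell markers had negative changes, with a mean of -2.09. Jchain, which joins antibody polymers, fell (-1.17), and 7 passed adjusted over the list alone (camera adjusted p = 0.000145, adjusted p = 0.521 with an estimated correlation). None of 11 T and NK cell markers passed by limma, with a mean of -1.04 and all changes negative, and 4 passed adjusted over the list alone (camera adjusted p = 0.000411, adjusted p = 0.593 with an estimated correlation). Kupffer BDL 3 again stood apart, at 4.56 for the B and plasma cell markers against 2.75 and 2.20 in the other BDL libraries, and at 3.47 for the T and NK cell markers, within the 3.42 to 3.74 of Sham.

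Over all 12748 genes tested in Kupffer-like cells, limma called 494, of which 188 rose and 306 fell, and 3070 had an unadjusted p under 0.05. The groups did not overlap for 4119 genes (32.3%), against 10% by chance. After scaling to a common sum 94 rose and 431 fell, and after scaling to recovered reads 132 rose and 494 fell, with the median of all genes moved by -0.32 and -0.18 log2 units. Limma called 0 genes without Kupffer Sham 1, 2 or 3 or Kupffer BDL 2, where 2281, 1752, 1814 and 2319 had an unadjusted p under 0.05, and 2272 without Kupffer BDL 3. With limma, 0 were called when all genes above 0 were tested (3254 at an unadjusted p under 0.05), 1 with sex as a covariate (2905), 0 with the hepatocyte markers as a covariate (790) and 0 with the B and plasma cell markers as a covariate (2743), while limma voom on recovered reads called 473. Neither marker covariate overlapped between Sham and BDL, so each also takes up the treatment contrast. The ranges were 3.65 to 5.10 and 5.44 to 6.81 for hepatocyte markers, and 5.13 to 5.36 and 2.20 to 4.56 for B and plasma cell markers.

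**Figure D2:**
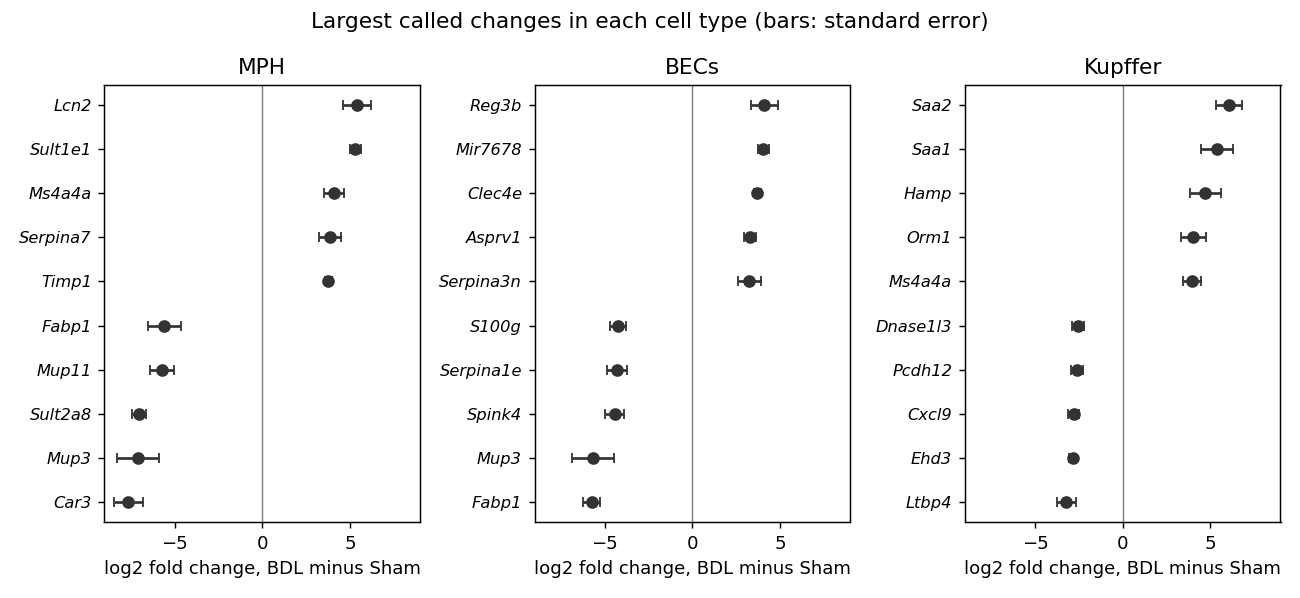
The 5 largest rises and 5 largest falls among called genes in each cell type, as log2 fold change of BDL against Sham on the x axis, with bars for the standard error. The values ran from -7.64 for Car3 to 5.40 for Lcn2 in MPH, from -5.76 for Fabp1 to 4.09 for Reg3b in BECs, and from -3.22 for Ltbp4 to 6.07 for Saa2 in Kupffer-like cells.

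**Figure D3:**
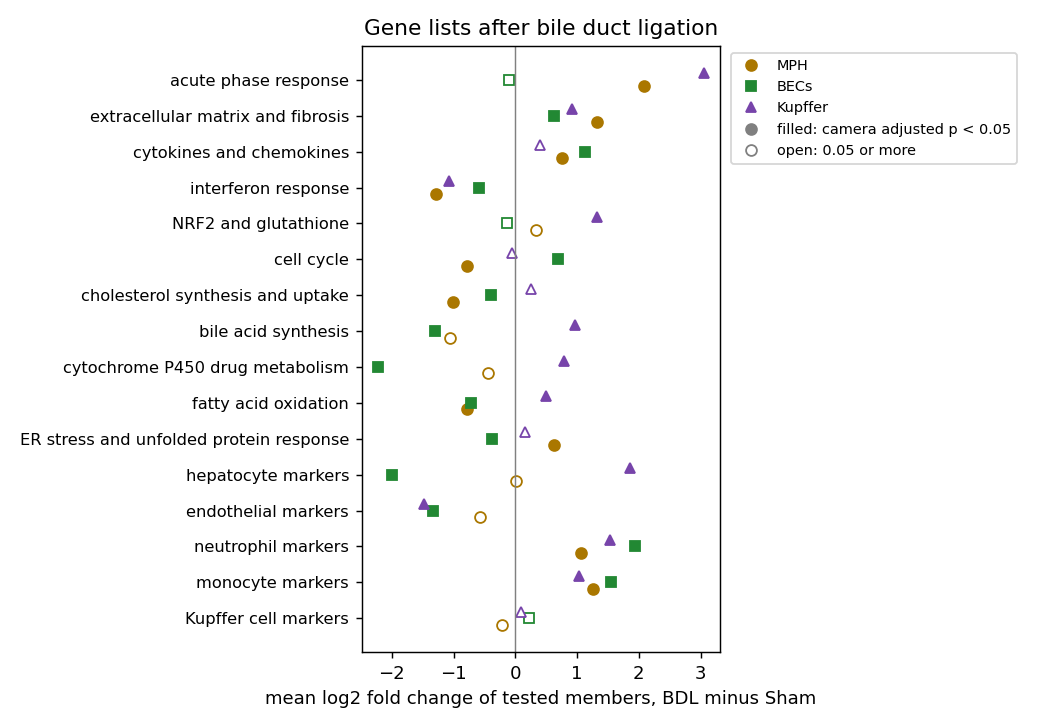
Mean log2 fold change of BDL against Sham over the tested members of 16 gene lists, with circles for MPH, squares for BECs and triangles for Kupffer-like cells, filled where the camera adjusted p was under 0.05 with the preset correlation. Interferon response genes had negative means in all 3 cell types (-1.28, -0.58 and -1.07), and hepatocyte markers had means of 0.02, -1.99 and 1.86; no list passed with an estimated correlation.

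The responses of pairs of cell types were compared by testing the difference itself. Between MPH and BECs it was called for 237 of 14780 genes, 131 more positive in MPH and 106 in BECs. Sult1e1 rose in MPH by 5.30 and was near 0 FPKM in both BECs groups, a difference of 5.20 (standard error 0.36, limma adjusted p = 0.000124), whereas S100g changed by 1.58 in MPH and -4.22 in BECs, and Spink4 by -0.05 and -4.44. The sulfotransferases Sult2a8 (-7.04 in MPH, -2.18 in BECs) and Sult5a1 (-3.38, -0.06) and the anion transporter Slc22a7 (-3.64, -0.18) differed the other way. In BECs Sham these 3 stood at 6.36, 0.707 and 0.164 FPKM, and S100g and Spink4 in MPH Sham at 0.190 and 0.111, where the offset of 1 FPKM limits the fall that can be seen. Sult2a8 went to 0.0216 FPKM in BECs BDL. Leaving out MPH Sham 1, MPH BDL 2, BECs Sham 1, BECs Sham 2, BECs BDL 1 or BECs BDL 2 gave 82, 51, 61, 64, 76 or 117 genes. The share more positive in MPH was 55.3%, and 65.4% after scaling to a common sum.

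Between MPH and Kupffer-like cells the response differed for 57 of 14101 genes, 6 more positive in MPH and 51 in Kupffer-like cells, and for 469 when the number shared by 3 pairs of libraries was used as a block. Eppk1, an epithelial plakin, changed by 2.30 in MPH and 0.15 in Kupffer-like cells (difference 2.15, standard error 0.24, limma adjusted p = 0.00882), Ccdc120 by 2.25 and 0.01 and Rapgef2 by 0.66 and -0.47. Dio1, a deiodinase that activates thyroid hormone, changed by -4.54 and -0.59 and Slc22a7 by -3.64 and -0.01. Dio1 and Slc22a7 stood at 1.26 and 0.167 FPKM in Kupffer Sham, so that little fall could be seen there. Mup11 fell in MPH. In Kupffer-like cells it stood at 0.137 FPKM in Sham, so that little fall could be seen, and was listed at 0 in the BDL libraries. Without Kupffer BDL 3 the count was 382, without Kupffer BDL 1 or 2 it was 20 or 14, without Kupffer Sham 1, 2 or 3 it was 8, 4 or 3, and without MPH Sham 1, MPH Sham 3, MPH BDL 2 or MPH BDL 3 it was 3, 2, 7 or 3. Scaling to a common sum gave 6 genes, 66.7% of them more positive in MPH against 10.5% before, and scaling to recovered reads gave 7.

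Between BECs and Kupffer-like cells the response differed for 520 of 14874 genes, 200 more positive in BECs and 320 in Kupffer-like cells. The apolipoprotein genes Apoa1 (-3.54 in BECs, 2.17 in Kupffer-like cells) and Apoa2 (-3.89, 1.39) and Saa2 (0.22, 6.07) differed most in that direction, with a difference for Apoa1 of -5.71 (standard error 1.13, limma adjusted p = 0.0306). The immunoglobulin segments Iglj1 (2.49, -3.40) and Ighj4 (2.79, -2.04), short genes of a repeated family, and Ltb, the lymphocyte cytokine lymphotoxin beta, (1.64, -1.96) differed the other way. In the same libraries the hepatocyte markers moved as given above, as did the B and plasma cell markers in Kupffer-like cells. In BECs the 6 tested B and plasma cell markers had a mean change of 0.28. None passed, over all genes or adjusted over the list alone (camera adjusted p = 0.592, adjusted p = 0.906 with an estimated correlation). The whole list stood at a mean log2(FPKM + 1) of 2.31 and 2.37 in BECs BDL 1 and 2 and 4.97 in BECs BDL 3. Without BECs Sham 1, 2 or 3 the count was 38, 290 or 316, without BECs BDL 1 or 2 it was 217 or 183, without Kupffer Sham 1, 2 or 3 it was 281, 44 or 38, and without Kupffer BDL 2 or 3 it was 229 or 1773. The share more positive in BECs was 38.5%, 72.7% after scaling to a common sum and 66.7% after scaling to recovered reads.

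A response common to the 3 cell types was counted over the 10847 genes tested in all of them. Of these 10 rose in each cell type, where independent lists would give 0.0245, and 1 fell in each, Asb2, where they would give 0.0540. The lists may not be independent, since 3 pairs of MPH and Kupffer-like libraries share a number in their titles, so both values can be too low. The rises held in all 3 were largest for Trem1, an activating receptor of neutrophils and monocytes, with log2 fold changes of 2.47, 2.86 and 3.12 in MPH, BECs and Kupffer-like cells. Ms4a4a (4.07, 2.29, 3.98), the chemokine receptor Ccr1 (2.18, 2.36, 2.34), Lcn2 (5.40, 2.01, 3.49) and the clotting factor subunit F13a1 (1.96, 2.20, 2.11) followed. Monocyte and neutrophil markers stood higher as groups in the same 3 comparisons with the preset correlation of camera but not with an estimated one (adjusted p = 0.369 to 0.593 with an estimated correlation). With fry the monocyte markers passed in all 3 (adjusted p = 0.0121 to 0.0498) and the neutrophil markers in BECs (adjusted p = 0.0297), not in MPH (0.328) or Kupffer-like cells (0.0619). In MPH 0 of 9 neutrophil markers passed by limma, also adjusted over the list alone. F13a1 is itself one of the monocyte markers. The total of 11 became 1 without MPH Sham 1 or 2, 3 without MPH BDL 1 or 3, 7 without BECs Sham 1, and 0 without MPH Sham 3, MPH BDL 2, Kupffer Sham 1, 2 or 3 or Kupffer BDL 2. In those last 6 cases 264, 159, 167, 149, 173 and 168 genes had an unadjusted limma p under 0.05 in 1 direction in all cell types. By limma the total was also 0 with no filter on level and 0 with sex as a covariate (222 and 201 at an unadjusted p under 0.05). With sex as a covariate 9, 10 and 0 of the 10 rises passed in limma in MPH, BECs and Kupffer-like cells, and 10 in each had an unadjusted p under 0.05.

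Pairwise, MPH and BECs shared 18 rises and 14 falls (1.84 and 3.16 for independent lists) and 3 genes went opposite ways (Eppk1, Adora1 and Dusp8, up in MPH), MPH and Kupffer-like cells shared 22 rises and 3 falls, Cd209f, Lifr and Asb2 (1.05 and 1.49), and BECs and Kupffer-like cells shared 46 and 35 (5.07 and 10.4) with 4 opposite (Sult1a1, Gpt2 and Cystm1, up in Kupffer-like cells, and Mapk11, up in BECs). The genes of these short overlaps were named after their values were seen. The values for independent lists do not allow for the 3 pairs of MPH and Kupffer-like libraries that share a number, so they can be too low for MPH and Kupffer-like cells. Across genes, which are not independent replicates, the log2 fold changes of MPH and BECs had a Pearson r of 0.389 (Spearman rho 0.334, 11349 genes), those of MPH and Kupffer-like cells 0.334 (0.217, 11216 genes) and those of BECs and Kupffer-like cells 0.0742 (0.138, 11777 genes). With a pseudocount of 0.01 the last was -0.00581.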

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

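The tests of acute phase genes, of Kupffer RNA in hepatocyte preparations of monocytes and neutrophils and of sex, and the scaling to recovered reads, were chosen only after the results were seen. The test of sex replaced a covariate for all 3 cell types, which cannot move the changes where both groups hold the same number of each sex. The way of counting splits for the correlations and for cell type identity was also revised after a first count, since mirror splits and exchanged cell type names had been counted as rivals. The count of 100 as large went from 8 to 6, 17 to 15 and 66 to 60 for the correlations and from 1 to 1, 2 to 4 and 2 to 4 for MPH, BECs and Kupffer-like cells, and on neither count did any of these move across 1 in 20.

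The response to ligation differed between cell types by a test of the difference itself for 237 genes between MPH and BECs, 57 between MPH and Kupffer-like cells (469 with the shared number as a block) and 520 between BECs and Kupffer-like cells. Between MPH and BECs the differences in log2 units were 5.80 for S100g, 5.20 for Sult1e1, 4.38 for Spink4, -4.86 for Sult2a8, -3.46 for Slc22a7 and -3.33 for Sult5a1. In BECs Sham, Sult2a8, Slc22a7 and Sult5a1 stood at only 6.36, 0.164 and 0.707 FPKM, so the offset of 1 FPKM limited their fall there and the size of these differences depends on it. Between MPH and Kupffer-like cells they were 2.24 for Ccdc120, 2.15 for Eppk1, 1.14 for Rapgef2, -5.54 for Mup11, -3.95 for Dio1 and -3.64 for Slc22a7. Mup11, Dio1 and Slc22a7 stood at 0.137, 1.26 and 0.167 FPKM in Kupffer Sham under the same limit, and Mup11 is listed at 0 in Kupffer BDL. Between BECs and Kupffer-like cells the differences were 5.88 for Iglj1, 4.83 for Ighj4, 3.60 for Ltb, -5.86 for Saa2, -5.71 for Apoa1 and -5.28 for Apoa2.

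Relabelling within cell types gave as many genes in 2, 4 and 2 of 100 labellings, the real ones included. Mixed labels also remove the response of each cell type. Relabelling therefore tests for any response and cannot exclude chance for a difference between 2 responses. The highest other counts were 2048, 425 and 1847 genes, well above the real ones. The 2048 and 1847 came from labellings that kept 1 cell type as it was and exchanged Sham and BDL in the other, which adds the 2 responses, and without such labellings the highest were 191 and 167. The 425 had mixed MPH labels and exchanged Kupffer labels. Among the 28 labellings that part as many same-numbered pairs of MPH and Kupffer-like libraries, the real 57 was the highest, with 9 next.

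For BDL against Sham, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 194 genes in MPH, 1040 in BECs and 494 in Kupffer-like cells, the highest other 0, 2 and 0 by limma, so that 1 of 10 was as large in each. For the 11 common genes 1 of 100 labellings was as large, with 0 the highest other. Other splits called at most 2 genes in any cell type, so a labelling that mixed any of them could give almost no common genes. This test therefore cannot exclude chance for the overlap. Its labellings also did not keep same-numbered MPH and Kupffer-like libraries together. For the genes of cell type identity, 1, 4 and 4 of 100 regroupings gave as many as the 3102, 2318 and 1898 genes of MPH, BECs and Kupffer-like cells. Regroupings that kept no cell type intact gave at most 0 genes by limma, since mixing cell types puts their differences into the spread. The test therefore excludes chance for any difference among the 3 cell types, and cannot do so for the count of each. The highest other was 2499 for each, from a regrouping that kept 1 cell type intact. For the correlations of responses chance could not be excluded: 6, 15 and 60 of 100 pairs of splits gave an r as far from 0 as 0.389, 0.334 and 0.0742, with highest others of 0.473, 0.493 and 0.251. Most of these pairs of splits part the same-numbered MPH and Kupffer-like libraries differently from the real one. Among the 28 labellings that keep each such pair under 1 treatment, 6 gave an r as far from 0 as 0.334, with 0.493 the highest other.

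Hepatocyte markers stood lower as a group in BECs and higher in Kupffer-like cells after ligation with the preset correlation of camera, but not with an estimated one (adjusted p = 0.545 for each), and in Kupffer-like cells 0 of 16 passed by limma (6 adjusted over the list alone). Scaling is argued against as the whole cause. The median change of the hepatocyte markers went from -2.02 to -1.96 in BECs after scaling to recovered reads. In Kupffer-like cells it went from 1.83 to 1.67. The standard errors after scaling, taken over the 16 markers, were 0.196 and 0.176. These markers moved together in the same libraries (estimated correlation 0.539 and 0.547). The standard errors therefore do not measure the spread between libraries. Over genes restricted to hepatocytes in Sham, the change followed that of MPH with r = 0.747 in BECs (89 genes, rank correlation 0.515, slope 0.474) and r = 0.911 in Kupffer-like cells (83 genes, rank correlation 0.830, slope 0.894), against r = 0.402 and 0.372 over other genes, so a different amount of RNA carried over from hepatocytes is a candidate explanation. Leaving out libraries gave r from 0.534 to 0.814 and slopes from 0.266 (without BECs Sham 1) to 0.537 in BECs, below the 1 that RNA with the MPH profile alone would give. In Kupffer-like cells it gave r from 0.676 to 0.923 and slopes from 0.467 (without Kupffer Sham 1) to 1.06. In BECs part of the change is therefore left open. The same holds in Kupffer-like cells, where a slope near 1 depends on Kupffer Sham 1. The acute phase genes of Kupffer-like cells lay at a median of -0.47 from the change such carry-over would give, with 6 of 21 above it. The standard error of 0.316 is again taken over genes, not libraries. The offset of 1 FPKM shrinks rises that start near 0, such as that of Saa2 from 0.450 FPKM in Kupffer Sham, so this test leans toward carry-over. The values go with the same source, and a response of the cells themselves stays open and was not tested.

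Kupffer cell markers stood at a median of 62.1% of their Kupffer-like level in MPH of sham mice, and of 39.8% without MPH Sham 1, the highest of the 3. Scaling may account for part of this, since 11 of 12 markers were higher in Kupffer-like cells than in both others after scaling to recovered reads. The median level in MPH was then still 36.7% (20.9% without MPH Sham 1). For RNA of Kupffer-like cells in the hepatocyte preparations, 11 of 12 markers lay within 1 log2 unit of their median ratio (12 without MPH Sham 1), as a single source would give. Expression in the hepatocytes themselves was not tested.

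The rise of 10 genes in all 3 cell types may in part reflect monocytes and neutrophils in all 3 preparations. The median change of the other monocyte and neutrophil markers was 0.460, 0.771 and 0.498 times that of these genes in MPH, BECs and Kupffer-like cells, and 8 of the 10 were highest in Kupffer BDL. The exceptions were Lcn2 (1101 FPKM in MPH BDL, 87.0 in Kupffer BDL) and Gm26809 (83.6 in BECs BDL, 27.7 in Kupffer BDL). The neutrophil markers stood at a mean log2(FPKM + 1) of 3.24 in MPH BDL and 5.49 in Kupffer BDL, the other way from Lcn2. Sex of the animals is argued against as the whole cause, since in 2 of the 3 cell types, MPH and Kupffer-like cells, as many libraries had Y-linked transcripts in BDL as in Sham. In BECs, with 1 against 2 such libraries, the median change of the 10 genes was 2.18 with sex as a covariate and 2.12 without (median standard errors 0.234 and 0.222), while in Kupffer-like cells 0 of 10 then passed by limma (10 at an unadjusted p under 0.05) at the same median of 2.22 (0.315 and 0.292) and 1 degree of freedom fewer. A shared response of the 3 cell types stays open and was not tested.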

How the results depend on the processing

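Scaling to recovered reads, limma voom with annotation lengths, the covariates of sex, endothelial and B and plasma cell markers, and leaving out libraries in the correlations were chosen only after the results were seen. No named gene or list that passed its test changed sign under any alternative run. Among those that did not pass, the sign differed in 38 of 2310 gene values and 34 of 574 list values, and fry gave 5 of 113 lists the opposite direction to camera. Of 113 list tests, the 55 called with camera all lost the call with an estimated correlation (smallest adjusted p = 0.369) and 37 lost it with fry, which gained 1. Of 306 named gene results, 158 lost the call with no filter, 104 with sex as a covariate and 3 with median ratio scaling. So did 137 of 205 with the hepatocyte marker covariate, 52 of 99 with the B and plasma cell covariate, and 727 of 1875 when 1 library was left out. These totals include genes that were not called in the main fit and so could not lose a call. For the counts below the cause was not tested, except that no filter tests more genes and leaving out a library leaves fewer. The hepatocyte covariate, and the B and plasma cell covariate in Kupffer-like cells, did not overlap between Sham and BDL and so also take up the treatment contrast.

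Called genes in MPH (194) went to 117 with a pseudocount of 0.1, 59 with 0.01, 18 with no filter, 115 after scaling to a common sum, 96 to recovered reads and 116 with voom, and about 2.2e+03 with all 18 libraries in 1 model. Those in BECs (1040) went to 81 with no filter, 576 with a 2-fold threshold, 576 with sex as a covariate and 8 with the hepatocyte covariate. Those in Kupffer-like cells (494) went to 323 and 286 with the smaller pseudocounts, 1222 with all libraries, and by limma to 0 with no filter, 1 with sex, 0 with the hepatocyte covariate and 0 with the B and plasma cell covariate (3254, 2905, 790 and 2743 at an unadjusted p under 0.05). The MPH count was 220 with the Kupffer marker and 237 with the endothelial covariate.

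Differences between MPH and BECs (237) went to 112 and 102 with the pseudocounts, 86 with no filter, 122 at FPKM of at least 5, 102 with voom and 414 with all libraries. Those between MPH and Kupffer-like cells (57) went to 11 and 12, 24 with no filter, 6 to a common sum, 7 to recovered reads, 35 by median ratio, 24 with quantile normalization, 89 without trend and robust, 7 with voom, 36 with sex, 716 with all libraries and 469 with the block. Those between BECs and Kupffer-like cells (520) went to 318 and 287, 13 with no filter, 226 with voom and 244 with sex. Common genes (11) went to 5 with a pseudocount of 0.01, 7 to a common sum and by limma 0 with no filter and 0 with sex (222 and 201 at an unadjusted p under 0.05). The correlation of BECs and Kupffer-like responses turned to -0.00581 with a pseudocount of 0.01.

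Genes of identity went to 1331 (BECs) and 1198 (Kupffer) at FPKM of at least 5, 1234 (MPH) and 3182 (Kupffer) after scaling to a common sum, 1559 (MPH) and 2916 (Kupffer) to recovered reads, and 1901, 1535 and 1035 with a 2-fold threshold. The 3 Kupffer markers became 1 with a pseudocount of 0.01, 5 by median ratio, 11 with scaling to a common sum, to recovered reads or quantile normalization, and 0 by limma with no filter (5 at an unadjusted p under 0.05).

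Leaving out 1 library gave 8 to 77 genes in MPH, 86 to 1033 in BECs, 0 to 2272 in Kupffer-like cells, 51 to 338, 2 to 382 and 38 to 1773 differences, 0 to 16 common genes, 2594 to 3003, 1203 to 2502 and 1104 to 2084 genes of identity, 0 to 12 Kupffer markers, and correlations of 0.298 to 0.451, 0.237 to 0.420 and 0.0107 to 0.138. The libraries that moved a count by over 1.5 times are named in the report beside that count. Depth was alike, from 15455411 to 20583319 reads, and 2-fold differences of response were recovered in 16.2% to 65% of simulated genes. The simulation had the spread of the Sham libraries only.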

Other observations

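The comparison of sex by shared number and the look at mitochondrial reads of single libraries were chosen only after the result was seen. Further gene groups moved after ligation. In BECs, Nr0b2 (-1.81), Rxra (-0.82) and Foxa2 (-0.71) fell among 10 liver nuclear receptors and factors, with 9 passing adjusted over the list alone (camera adjusted p = 3.60e-05, adjusted p = 0.434 with an estimated correlation). Acadm (-0.82), Eci1 (-0.80) and Acaa1b (-2.78) fell among 16 fatty acid oxidation genes and G6pc (-2.75), Glul (-0.69) and Otc (-1.32) among 13 genes of gluconeogenesis and the urea cycle, with 7 and 8 passing adjusted over the list alone (camera adjusted p = 7.57e-05 and 0.000622, adjusted p = 0.434 and 0.545 with an estimated correlation), while the hepatocyte markers of the same libraries had a mean change of -1.99. Mdm2 (0.95), Lmnb1 (1.15) and Cdkn2b (0.78) rose among 11 p53 and senescence genes, with 4 passing adjusted over the list alone (camera adjusted p = 0.000977, adjusted p = 0.521 with an estimated correlation). Herpud1 (-0.81) and Atf4 (-0.63), of the unfolded protein response, fell among 15 such genes in BECs, with 4 passing adjusted over the list alone (camera adjusted p = 0.00461, adjusted p = 0.593 with an estimated correlation).

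In MPH, none of those 15 unfolded protein response genes passed by limma, over all genes or adjusted over the list alone, and 14 had positive changes with a mean of 0.63 (camera adjusted p = 0.00611, adjusted p = 0.545 with an estimated correlation). Cd9 (2.01) and Gpnmb (2.88) rose among 10 markers of lipid- and scar-associated macrophages in MPH, with 5 passing adjusted over the list alone (camera adjusted p = 0.000411, adjusted p = 0.409 with an estimated correlation), and Krt7 (1.13) among 6 biliary markers, with 3 passing adjusted over the list alone (camera adjusted p = 0.00541, adjusted p = 0.434 with an estimated correlation). In Kupffer-like cells Trf (1.92), the iron carrier transferrin, and Hamp (4.72) rose among 11 iron handling genes, with 5 passing adjusted over the list alone (camera adjusted p = 0.00443, adjusted p = 0.545 with an estimated correlation), beside a mean change of 1.86 of the hepatocyte markers. All 13 mitochondrial transcripts had positive changes there, with a mean of 1.17 and none passing by limma over all genes or adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.686 with an estimated correlation), and mitochondrial reads made up 3.84%, 1.57% and 1.60% of Kupffer Sham 1 to 3 and 2.54%, 7.61% and 1.72% of Kupffer BDL 1 to 3, high in BDL 2 alone. Of all 113 list tests camera called 55, 33 up and 22 down, and 58 were not called (camera adjusted p from 0.0627 to 0.990). The mean or the median change differed in sign from the direction of the test in 11 of 113, none of them among the 55.

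Libraries with Y-linked transcripts were 2 of 3 in both MPH groups, 2 of 3 in BECs Sham, 1 of 3 in BECs BDL and 1 of 3 in both Kupffer groups. Numbers in the titles were shared by 3 pairs of MPH and Kupffer-like libraries, which had the same sex within each pair and correlations of 0.230, 0.337 and 0.305 after group means were removed. Each of these 6 libraries correlated best with the library of the same number. Genes above 0 numbered 19167 in MPH Sham 1, the fewest, and 34809 in Kupffer Sham 2, which stood apart from the next highest, BECs BDL 1 (25600). Genes with 1 read numbered 5051 in Kupffer Sham 2, again the most, and 3093 in BECs BDL 1, the next highest. Beyond leaving Kupffer Sham 2 out, its effect on the Kupffer results was not tested.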
